A study of Mus musculus with 2 samples.

How the data were processed

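RNA was sequenced from bone marrow derived mast cells of C57BL/6 mice, 1 library from WT cells and 1 from Tet2-/- cells. Per the labels' protocols, femoral marrow was grown for 4 to 6 weeks with 10% serum, stem cell factor at 5 ng/ml and interleukin-3 at 10 ng/ml, cells more than 97.5% positive for the IgE receptor and c-Kit were used, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. Whether the kit kept strand is not stated, so sense and antisense reads are treated as inseparable. Among the named genes this also bears on Il4ra, Cish, Cd55, Slc18a2, Ikzf2, Herpud1, B2m, Tbp, Tpi1, Aldoa, Mettl3, Lyn, Tulp4, Mitf, Top2a and Mir6363, which overlap a gene on the opposite strand.

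The authors deposited 1 table of RPKM values, reads scaled to the length of the gene model and to the mapped reads of the library, with a column per genotype, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the gene annotation are not given in the sources used here. RPKM corrects for gene length and total reads, so a gene that takes a large share of reads lowers the values of others, and very short models receive unstable values. The value 0.01 stood for 58.1% of the models in WT and 57.4% in Tet2-/- and was read as a substituted value for models with no reads, although 67 models in WT and 80 in Tet2-/- lie below it, so it is not the lowest value and this reading is uncertain. Only 8139 symbols are in the table, of which 3742 are protein-coding genes. They include 17.1% of annotated protein-coding genes and between 14.9% and 19.0% of those on each autosome and X. Other genes were not analysed here. Of the symbols, 7861 matched GENCODE mouse release 21, whose build is the same as mm10, and 278 did not.

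Depth was recovered from the low values. For genes with a single annotated transcript, RPKM times effective length times depth fell within 0.1 of a whole fragment for 96.3% of 298 genes in WT at 31100000 fragments, and for 98.0% of 302 genes in Tet2-/- at 32000000, where chance gives 20%. The depth ratio was 1.03. A value of 1 RPKM in a 2 kb transcript then stands for 62.2 and 64 fragments. These depths are inferred and were not stated by the submitters. Fragment numbers for the intervals used the shortest basic transcript, a protein-coding one for protein-coding genes, which gives fewer fragments and wider intervals. No estimate was made where that transcript was shorter than 400 bases or the symbol matched more than 1 model. The 95% interval of each ratio is an exact Clopper-Pearson interval of the share of fragments in 1 library. It covers counting error only.

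Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, so that a gene near 1 RPKM needs a ratio well above 2 to count, whereas ratios are of the RPKM values. Genes entered with a mean of at least 1 RPKM and counted as higher or lower at a log2 fold of at least 1 in size, a fixed rule of size in place of a test. Each of 27 gene lists, which hold 480 distinct genes, was described by its median log2 fold and, with at least 3 members past the filter, by its percentile among 10000 random lists of the same size matched on 20 bins of mean expression. Of the list genes, 84 are in the table. The design, lists, naming rule and most alternatives were fixed before the data were examined.

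Genes were named by rule. The rule took Tet2, the 12 models most higher and the 12 most lower among those reaching 10 RPKM in the higher library, up to 4 members of each list reaching 10 RPKM, and the SOCS family with Gata1, Gata2, Mitf, Kit, Fcer1a, Ms4a2, Il3ra and Csf2rb where listed. Predicted models, pseudogenes, receptor segments and sex-linked genes were left out of the ranking. The 12 most higher and lower among protein-coding genes alone were added after the values were seen, as was the naming of lineage markers below 10 RPKM. Single values of some genes that the rule or the lists took are not reported here, although the genes stay in the counts and medians.

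The calling rule was tested on simulated data made from the WT and Tet2-/- values with 2120 genes, the changed ones drawn from genes with a mean of at least 5 RPKM. The simulation holds counting error only, so it checks the calculation and not how often real differences between cultures would be called. All 67 genes changed 3-fold and all 70 changed 4-fold were called, 0 of 63 changed 1.5-fold were called, and 0 of 1920 unchanged genes were called. Models shorter than 400 bases were simulated as 400 bases long, so these numbers do not cover the instability of very short models. The simulated depth of each library was recovered exactly. The alternatives tried were other pseudocounts, filters, fold thresholds and a median-ratio scaling, and restrictions to protein-coding genes and to models not at 0.01 in either library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.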

Results

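Gene expression was measured by RNA sequencing in mast cells grown from the bone marrow of C57BL/6 mice, 1 library from wild type (WT) cells and 1 library from cells lacking Tet2 (Tet2-/-). Mast cells are tissue-resident myeloid cells that carry the high-affinity IgE receptor and the stem cell factor receptor c-Kit, and Tet2 encodes an enzyme that oxidises 5-methylcytosine in DNA. The comparison asks how the mast cell transcriptome differs without Tet2. The values were RPKM for 8139 gene symbols, 17.1% of annotated protein-coding genes being among them, so every count refers to the listed genes. The spacing of low values implied 31100000 fragments in the WT library and 32000000 in the Tet2-/- library. With 1 library per genotype, no difference has a replicate check and no p-value is given. The bracketed 95% intervals are exact counting intervals of the ratio, which cover counting error only and not the spread between cultures or mice.

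Tet2, the targeted gene, is not among the listed symbols and was not analysed here, so the genotype labels have no check from the expression values. Of the fixed list of DNA methylation and demethylation enzymes, 1 gene was listed, Idh1, which stood at 17.9 RPKM in WT and 16.8 RPKM in Tet2-/-.

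Expression was similar in the libraries for most genes, with a limited set far apart. Of 2107 gene models with a mean of at least 1 RPKM, 61 were higher by 2-fold or more in the Tet2-/- library and 34 were lower, on the log2(RPKM + 1) scale. The median log2 fold was 0.01, and 90.6% of models lay within 1.5-fold. Across genes, which are not independent replicates, Pearson's r was 0.94 and Spearman's rho 0.95. Among the 1759 protein-coding genes with a transcript of at least 500 bases, a restriction chosen after the values were seen, 30 were higher and 16 lower. The remaining 348 models gave 31 higher and 18 lower.

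**Figure D1:**
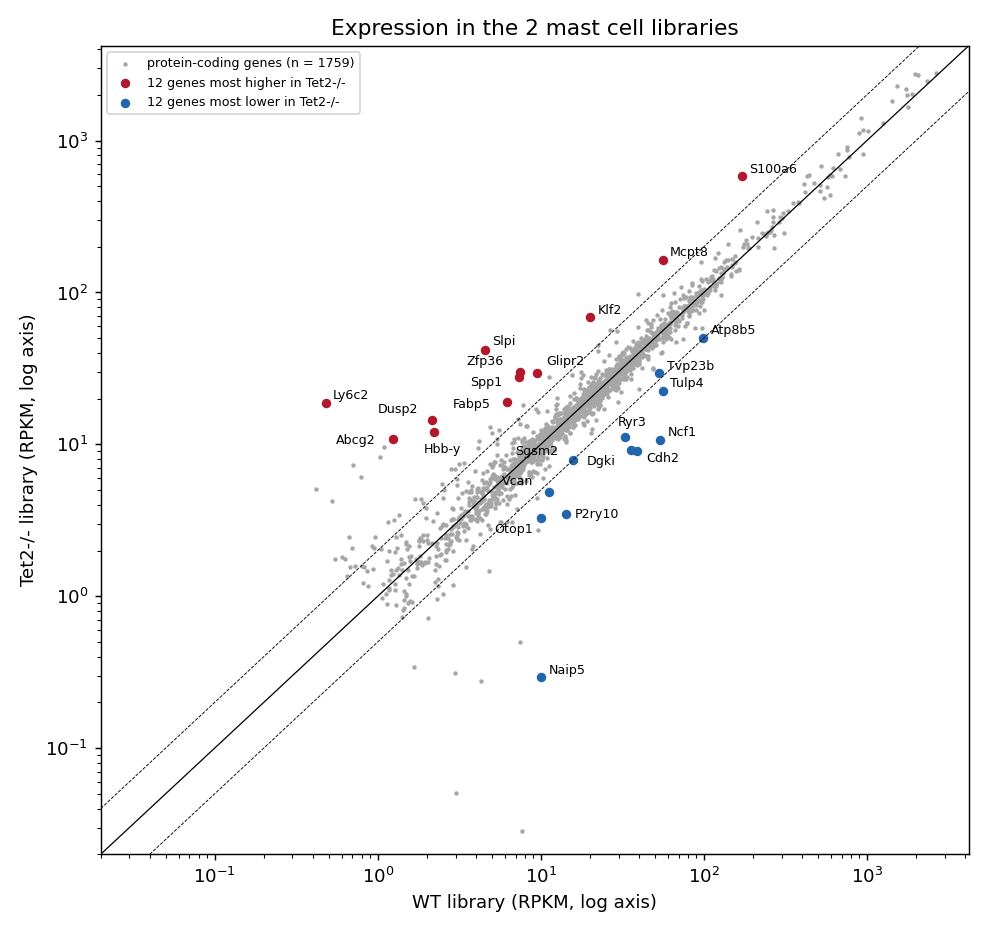
RPKM in the Tet2-/- library (vertical, log axis) against RPKM in the WT library (horizontal, log axis) for 1759 protein-coding genes, 1 point per gene, with the solid line at equal values and dashed lines at a 2-fold ratio of the RPKM values. Red and blue points are the 12 genes most higher and the 12 most lower in Tet2-/- among those reaching 10 RPKM, such as Ly6c2 (0.479 and 18.8 RPKM) and Naip5 (10.1 and 0.292 RPKM).

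Among protein-coding genes reaching 10 RPKM, those standing highest in the Tet2-/- library relative to WT were led by Ly6c2, Slpi and Abcg2. Ly6c2, a monocyte surface antigen gene (chromosome 15, 75108158 to 75111970, mm10), was at 0.479 RPKM in WT and 18.8 RPKM in Tet2-/-, a ratio of 39.3 (18.2 to 134). Slpi, which encodes a secreted inhibitor of leukocyte proteases (chromosome 2, 164354070 to 164389095), was at 4.56 and 41.8 RPKM, a ratio of 9.17 (6.74 to 12.8). Abcg2, an efflux transporter gene (chromosome 6, 58584523 to 58695676), was at 1.25 and 10.9 RPKM, a ratio of 8.73 (6.89 to 11.2). The phosphatase gene Dusp2 was at 2.15 and 14.5 RPKM, a ratio of 6.77 (5.44 to 8.43). Hbb-y, an embryonic globin gene, was at 2.22 and 12.1 RPKM, a ratio of 5.44 (3.71 to 8.19). Among protein-coding genes alone the next were Zfp36, which encodes an RNA-binding protein that destabilises cytokine mRNAs, at 7.47 and 30.1 RPKM, and Spp1, which encodes osteopontin, at 7.35 and 27.8 RPKM. The transcription factor gene Klf2 was at 20.1 and 68.5 RPKM, the calcium-binding protein gene S100a6 at 170 and 581 RPKM, Glipr2 at 9.46 and 29.7 RPKM, and the fatty acid binding protein gene Fabp5 at 6.17 and 18.9 RPKM. Ly6c2, Hbb-y and Fabp5 have close paralogs or pseudogene copies, and their values are uncertain to the extent that reads were shared. Zfp36 overlaps an annotated antisense RNA, whose reads cannot be told apart from its own.

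Those standing lowest in the Tet2-/- library relative to WT, again among protein-coding genes reaching 10 RPKM, were led by Naip5, Ncf1 and Cdh2. Naip5, an inflammasome sensor gene (chromosome 13, 100211739 to 100246323), was at 10.1 RPKM in WT and 0.292 RPKM in Tet2-/-, a ratio of WT to Tet2-/- of 34.5 (25.8 to 47.1). It lies in a family of close paralogs, so its value is uncertain. Ncf1, which encodes a cytosolic subunit of the phagocyte NADPH oxidase (chromosome 5, 134220053 to 134229625), was at 54.2 and 10.8 RPKM, a ratio of 5.04 (4.69 to 5.43). Ncf1 overlaps Gtf2ird2 on the opposite strand, which was at 6.78 and 7.31 RPKM. Cdh2, the gene of N-cadherin (chromosome 18, 16588877 to 16809246), was at 39.0 and 9.04 RPKM, a ratio of 4.32 (4.04 to 4.62). The diacylglycerol kinase gene Dgki was at 35.5 and 9.13 RPKM, the receptor gene P2ry10 at 14.2 and 3.48 RPKM, and the calcium channel gene Ryr3 at 32.8 and 11.2 RPKM. Otop1, a proton channel gene, was at 10.0 and 3.27 RPKM, Tulp4 at 56.4 and 22.5 RPKM, and Vcan, which encodes the matrix proteoglycan versican, at 11.2 and 4.84 RPKM. Atp8b5 was at 99.1 and 50.2 RPKM, Sgsm2 at 15.7 and 7.88 RPKM, and Tvp23b at 53.3 and 29.4 RPKM. Ryr3 overlaps Aven, and Cdh2, Dgki and Vcan overlap annotated antisense RNAs or pseudogenes, so these values may hold reads of both.

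Most listed mast cell genes differed by less than 1.5-fold, but many genes of these lists were not listed. The listed ones were 8 of 25 receptor and mediator genes, 3 of 14 granule proteases and 4 of 26 transcription factors. Kit, Fcer1a, Ms4a2, Gata1, Gata2, Il3ra and Csf2rb are not among the listed symbols and were not analysed here. Of the 7 genes past the filter on the mast cell receptor and mediator list, 1, Smpx, was higher by 2-fold or more and none was lower. The list's median log2 fold was -0.05, at percentile 6.41 of random lists matched on expression, and -0.03 with no filter. Smpx was at 4.18 RPKM in WT and 10.5 RPKM in Tet2-/-, Fcer1g, the shared gamma chain of Fc receptors, at 594 and 438 RPKM, Cd55 at 432 and 581 RPKM, and the vesicular monoamine transporter gene Slc18a2 at 572 and 491 RPKM. Among granule proteases, 2 of the 3 listed genes passed the filter. Mcpt8, also the only listed gene of the basophil markers, was at 56.1 and 163 RPKM, a ratio of 2.91 (2.72 to 3.11), while Gzmb, which encodes granzyme B, was at 1770 and 1994 RPKM. The 4 myeloid and mast cell transcription factors had a median log2 fold of 0.09 (percentile 82.1), with Mitf at 31.3 and 30.9 RPKM, Ikzf2 at 32.1 and 35.7 RPKM, and Gfi1b at 32.5 and 33.2 RPKM. The intervals of Mitf and Gfi1b included a ratio of 1. The listed IgE receptor signalling genes, Lyn at 49.6 and 48.5 RPKM and Dok1 at 16.3 and 17.2 RPKM, had intervals that included 1 as well.

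Markers of macrophages, neutrophils and eosinophils were at most 1.10 RPKM in WT and mostly higher in Tet2-/-. All 6 listed macrophage and monocyte markers had a counting interval above 1, although of these only Ly6c2 passed the filter. Csf1r was at 0.122 RPKM in WT and 1.32 RPKM in Tet2-/-, a ratio of 10.9 (6.28 to 20.3), C1qb at 0.105 and 1.51 RPKM, Mrc1 at 0.0802 and 0.775 RPKM, and Msr1 at 0.200 and 0.944 RPKM. Of the neutrophil and granulocyte precursor markers, Ly6g was at 1.10 and 9.61 RPKM, Mpo was at 0.01 in WT and 0.458 RPKM in Tet2-/-, and Csf3r was at 0.01 in both. Ly6g has no fragment estimate and so no interval. The doubt about shared reads given for Ly6c2 may apply to it as well, although sequence similarity was not examined. Of the macrophage, neutrophil and eosinophil markers only Ly6c2 and Ly6g passed the filter. If they shared reads, they would not be separate signals. Of the eosinophil markers, Ear2 was at 0.117 and 1.45 RPKM, on an estimated 2 and 25 fragments, and Il5ra at 0.712 and 0.820 RPKM with an interval that included 1. The cultures were described as more than 97.5% positive for both mast cell receptors. Lymphocyte, progenitor, stromal and sex-linked lists had 3, 1, 2 and 1 listed genes, none with an interval beyond 1. The erythroid and megakaryocyte list had 1 listed gene, the platelet gene Ppbp at 0.01 in both, so it assessed no erythroid gene, and the globin gene Hbb-y, which is outside the list, had a ratio of 5.44. The MHC class II and dendritic cell lists had none.

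**Figure D2:**
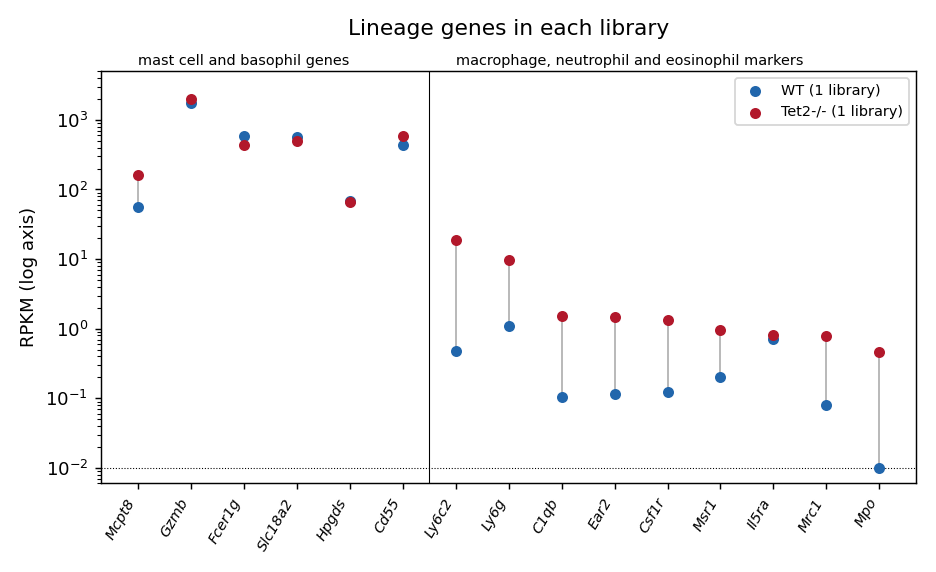
RPKM (vertical, log axis) of mast cell and basophil genes (left) and of the macrophage, neutrophil and eosinophil markers given in the text and detected (right) in the WT library (blue) and the Tet2-/- library (red), 1 library each, with a dotted line at the substituted value of 0.01. Csf1r, for example, lies at 0.122 and 1.32 RPKM, while Gzmb lies at 1770 and 1994 RPKM.

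Cytokine signalling genes went in both directions. The 7 listed JAK-STAT and SOCS genes had a median log2 fold of -0.07 (percentile 9.42), and none reached 2-fold. Cish, a STAT5-induced feedback inhibitor, was at 95.6 RPKM in WT and 158 RPKM in Tet2-/-, a ratio of 1.66 (1.61 to 1.70), and the interleukin-4 receptor gene Il4ra at 312 and 246 RPKM. Bcl2l1 was at 24.7 and 28.9 RPKM, Stat2 at 11.2 and 9.88 RPKM, and Socs7, the listed SOCS gene besides Cish, at 6.52 and 6.84 RPKM with an interval that included 1. Of the cytokine genes, Vegfa was at 48.7 and 31.5 RPKM, Ccl4 at 1.70 and 4.37 RPKM, and the other 4 listed were at 0.01 in both.

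Of the 3 immediate early and heat shock genes past the filter, 2 were higher by 2-fold or more, the immediate early genes Dusp2 and Zfp36, and the heat shock gene Dnajb1 was at 31.6 RPKM in WT and 38.7 RPKM in Tet2-/-. The list's median log2 fold was 1.88 (percentile 99.9), and 1.08 with no filter, when Hspa1b, another heat shock gene, joined it. All 3 glycolysis genes were lower in Tet2-/-, with a median log2 fold of -0.45 (percentile 0.33). Aldoa was at 685 and 429 RPKM, Tpi1 at 268 and 196 RPKM, and Ldha at 688 and 651 RPKM. Both lists rest on few genes, and Aldoa matched more than 1 annotated model.

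The 5 cell cycle genes had a median log2 fold of 0.10 (percentile 75.6), with Top2a at 119 RPKM in WT and 139 RPKM in Tet2-/-, Pcna at 214 and 230, Aurkb at 33.8 and 36.4, and E2f1 at 16.0 and 14.9. The 3 p53 target genes had a median of 0.18 (percentile 89.5), with Phlda3 at 17.7 and 29.9 RPKM, Sesn2 at 17.1 and 19.5, and Mdm2 at 43.7 and 47.9. The 3 unfolded protein response genes had a median of 0.14 (percentile 87.8), with Sdf2l1 at 84.4 and 93.4 RPKM and Herpud1 at 95.9 and 104. The 3 interferon response genes past the filter had a median of 0.25 (percentile 93.0), with Ifi27l2a at 15.7 and 18.8 RPKM, and the median was 0.10 with no filter, when all 8 listed members entered. The 4 cholesterol genes had a median of 0.01 (percentile 41.3), which turned to -0.001 under median-ratio scaling, with Mvk at 21.03 and 24.8 RPKM, Msmo1 at 60.3 and 62.3, and Stard4 at 57.7 and 56.1. The 4 housekeeping genes had a median of 0.21 (percentile 81.6), with Ppia at 1528 and 2272 RPKM, B2m at 665 and 821, Tbp at 23.6 and 20.5, and Actb at 1879 and 2029. The RNA methyltransferase gene Mettl3, the listed member of the RNA modification list, was at 22.5 and 21.3 RPKM. None of these genes reached 2-fold.

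**Figure D3:**
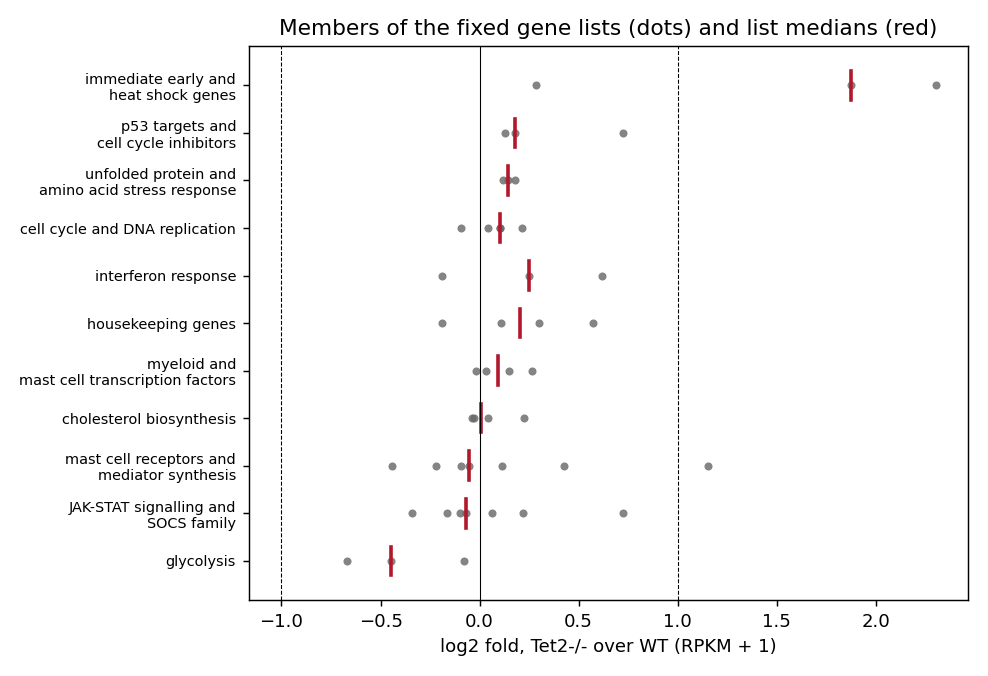
Log2 fold of Tet2-/- over WT on the log2(RPKM + 1) scale (horizontal) for the members past the filter of the 11 fixed lists with at least 3 such members, 1 dot per gene, with the list median as a red bar and dashed lines at a 2-fold difference. The immediate early and heat shock list has a median of 1.88 and the glycolysis list a median of -0.45.

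Small RNA models led the ranking of all models. The snoRNA models Snord104, Snord59a, Snord89 and Snord13, the mitochondrial tRNA gene mt-Ty and the microRNA model Mir6363 were listed at 0.01 in WT and at 801, 248, 42.0, 15.4, 583 and 58.4 RPKM in Tet2-/-. Mir7007, which lies within Cpa3, and the antisense RNA BC018473 were at 318 and 105 RPKM in WT and at 0.01 in Tet2-/-. The ribosomal RNA model Rn18s-rs5 was at 106 and 636 RPKM. No ratio is given for a model at 0.01. Snord59a lies within Atp5b, and reads of a host gene and a small RNA inside it cannot be separated here.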

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

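The restrictions to protein-coding genes and to models not at 0.01 in either library were chosen after seeing the data. The main counts were 61 models higher and 34 lower in Tet2-/-. Stricter settings gave fewer by construction, 33 and 14 with a pseudocount of 5, 40 and 16 with a mean of at least 5 RPKM, and 27 and 10 at 4-fold, and a 1.5-fold threshold gave 123 and 76. Protein-coding genes of at least 500 bases gave 30 and 16, as the 348 models left out held the other 31 and 18. Counts stayed within 1.5 times the main ones with a pseudocount of 0.1 (90 and 46), no filter (68 and 42), median-ratio scaling (61 and 35) and models at 0.01 in either library left out (44 and 28). Of 55 alternative list medians, 54 stayed within a factor of 1.5 in fold and 1 moved, the immediate early and heat shock list with no filter (1.08). Of 219 alternative values of 73 named genes, 194 stayed and 25 moved, all 25 under another pseudocount, and 0 changed direction. That 0 was largely fixed in advance. A pseudocount cannot change the sign of a fold, and the scaling shifted each log2 fold by only 0.0092. No TMM scaling was run, because the table holds no counts. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out. At the implied depths a gene near 0.1 RPKM rests on few fragments, and the interval of C1qb runs from 4.62 to 72.6.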

Other observations

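The tests of library scaling, of other myeloid cells, of expression within mast cells, of short models and of poly(A) selection were chosen only after the result was seen, as were the genes named in the next paragraph and the RNAs without a poly(A) tail named beside the histone genes. The spread required of the ribosomal protein differences was also set after those differences were seen, and it changed the outcome for transcript length, whose difference of 0.13 met the bound of 0.1 set beforehand against that explanation but did not clear it by more than its spread.

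Several weakly expressed genes that the naming rule did not reach differed widely. Atp9a, a phospholipid flippase gene, was at 7.68 RPKM in WT and 0.0286 RPKM in Tet2-/-, Tlr6, a receptor for bacterial lipopeptides, at 4.30 and 0.277 RPKM, and Il1r2, the interleukin-1 decoy receptor gene, at 3.01 and 0.0504 RPKM. Hic1, a transcriptional repressor gene, was at 9.65 and 2.72 RPKM, and Il2ra, the interleukin-2 receptor alpha chain gene, at 4.84 and 1.47 RPKM. Higher in Tet2-/- were the lysosomal protease gene Ctss, at 1.03 and 8.22 RPKM, Palld at 0.417 and 5.10 RPKM, and Prex1 at 0.525 and 4.27 RPKM. Of protein-coding genes, 11 were under 0.3 RPKM in WT and at 1 or more in Tet2-/-, and 8 the reverse. Of 20 protein-coding genes past the filter within 20 Mb of Tet2 on chromosome 3, 1 (5%) lay beyond 2-fold, against 2.59% of 1739 elsewhere. The share elsewhere would give 0.52 such genes near Tet2, so 1 gene does not separate these shares. Whether DNA around the targeted locus adds differences cannot be told.

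Macrophage, neutrophil and eosinophil markers were higher in the Tet2-/- library. The tables argue against a difference in scaling, since the median log2 fold of all genes past the filter was 0.0092. They also argue against a general gain of weak genes. On the log2(RPKM + 0.1) scale, 203 other protein-coding genes with a mean of 0.234 to 1 RPKM had a median log2 fold of 0.10. The lower bound was the lowest mean of a marker, that of Mpo, and each gene had a transcript of at least 500 bases. The markers' median on that scale was 2.51, at percentile 100 of matched random lists. Their lists were pooled because they stood high, so this percentile restates the pattern. Of the 9 markers with a fragment estimate, 8 had an interval above 1 and 0 below, while Csf3r stayed at 0.01 in both and Il5ra did not separate, but this count restates the pattern and favours no explanation. More cells of other myeloid types in the Tet2-/- culture and changed expression within the mast cells cannot be told apart for the 10 detected markers, because a bulk library gives no level per cell. A Tet2 effect and a difference between single cultures both stay open.

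Models at 0.01 in one library and at 10 RPKM or more in the other numbered 11, 9 of them higher in Tet2-/-. Length below the size of the sequenced fragments may be the source, as 90.9% were shorter than 200 bases against 1.77% of all models past the filter, but not for BC018473, which is 4753 bases long and had an estimated 3798 fragments in WT. Model length is the same in both libraries, but the implied mean fragment length was 170 bases in WT and 180 bases in Tet2-/-. Whether that difference accounts for 9 of the 11 being higher in Tet2-/- was not tested. Less complete poly(A) selection in the Tet2-/- library stays open, since 76.9% of 13 detected histone genes, whose transcripts lack a poly(A) tail, were higher there but only 2 had an interval above 1. Of other RNAs without such a tail, Rn18s-rs5 was at 106 and 636 RPKM and Rpph1 at 0.212 and 2.85 RPKM, while the mitochondrial tRNA gene mt-Te went the other way, at 1439 and 906 RPKM. No biological explanation was tested.

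Ribosomal protein genes were higher in Tet2-/- in 13 of 14 cases, with a median log2 fold of 0.29. The tables argue against a trend with GC content as the whole cause, since the difference from the 20 genes nearest in GC content was 0.26 (95% interval over resampled genes 0.11 to 0.37). A trend with transcript length stays open and may account for part. The difference from genes nearest in length was 0.13 (0.0019 to 0.21). The 69 other genes of at most 1000 bases had a median of 0.21, against 0.00081 for the 1675 longer ones. Both intervals resample the ribosomal protein genes, which are not independent replicates, with 1 library per genotype. They do not cover the spread between cultures or mice. Reads shared with processed pseudogenes and an effect of the genotype were not tested. A shift with length may also enter the values of short named genes, such as B2m at 860 bases with a log2 fold of 0.30.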
